A study of Oryza sativa Indica Group with 5 samples.

How the data were processed

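RNA of developing rice seed (Oryza sativa, Indica group) was measured on 5 custom single-colour Agilent rice arrays, each hybridised with Cy3-labelled material of another rice accession. Per the labels' protocols, the plants grew in a glasshouse at 29 °C by day and 21 °C by night, seed was taken 16 days after flowering, and total RNA came from 200 mg of ground seed. Per the labels, 3 accessions carry haplotype 8 and have high-amylose grain, and 2 carry haplotype 4 and have waxy grain, whose starch holds little or no amylose. Replicate numbers here follow the order of the deposits and pair no array with another. Because each array is another accession, p-values measure the spread between these accessions, which holds their genetic differences as well as technical differences between arrays. Both waxy arrays were scanned on a date of their own, so a group difference also holds any difference between scan dates. The p-values cannot set this part apart. No accession was measured on more than 1 array.

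The scanner values are intensity per spot, deposited by the authors as Agilent Feature Extraction output (version 11.5.1.1, protocol GE1_1105_Oct12, per the file headers). The processed intensity is background-subtracted and detrended within an array and is not normalized between arrays, per the file headers. Per the file headers, the output also holds 0 or 1 flags for spots that are well above background, saturated or outliers. A table of log2 values for the same arrays was deposited by the authors as well, and the submitters' processing notes name limma without a version. Its normalization is not given in the sources used here. Differences between its columns followed differences of quantile-normalized log2 processed intensity, with r of 0.9997 to 0.9998 across probes and slopes of 0.989 to 0.992 over the 10 pairs of arrays. Its column medians were -0.0172, 0.0395 and 0.0270 for high-amylose replicates 1, 2 and 3, and -0.0227 and 0.00414 for waxy replicates 1 and 2. The scale and direction are thus settled by comparison, and the baseline subtracted from each probe stays unknown. These values served as an alternative.

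Each array held 61657 spots that were not controls, for 59676 probes of 48857 loci with names of the MSU rice annotation. The grid belongs to the IRGSP5 build, per the file headers. No coordinates of that build were used here, so positions are given only as the chromosome in the locus name and as the order of locus names along it. Control spots were left out, and saturated spots were not removed. Spots of a probe were averaged without outlier spots, which were kept where all spots of the probe on that array were outliers. The value used is log2 of the processed intensity minus the array's 75th percentile of it. Outlier spots, 23 to 67 per array, stayed in that percentile. A probe was tested if it was well above background on at least 2 arrays, which kept 35634 probes. A locus with several probes was represented by the probe with the highest mean, which left 28945 loci. At 6319 loci with 2 or more tested probes, the probes gave opposite signs at 2258 loci and differed by over 2 on the log2 scale at 72. The deposited probe names fall into the classes JUNQ, JMULT and JXHYB, which the sources used here do not define.

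The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 5 arrays, no covariate), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences are high-amylose minus waxy. Other tools were jsonlite 2.0.0, version 1.17.8 of the data.table package, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The design makes 10 splits of the 5 arrays, so an exact permutation test of a single value cannot go below 0.1, and adjusted p-values come from limma, which pools the spread over loci. A locus that was not well above background on any array of a group has only a bound there. Its fold is then written as at least N-fold, the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the locus's own signal. Where the locus's own signal is the higher on every array of the dim group, this equals the measured fold, which is then given without a bound. Fitted log2 values of such loci are given as measured. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Chromosomes were tested with Fisher's exact test. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.463.

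The groups, the test, the threshold and the rule for named genes were fixed before the data were examined, as were the lists of starch synthases, of starch branching and debranching enzymes and phosphorylases, of ADP-glucose and sugar supply, and of endosperm regulators. The other 10 lists were written after the loci on the array were known and before any value was compared. They are glutelins, prolamins, globulins and allergens, sugar transport, starch breakdown, heat shock and chaperones, reference genes, and markers of 3 other seed parts or pathways, which are embryo and aleurone, photosynthesis of the green outer layers, and the flavonoid pathway. Planned keyword lists could not be matched, since no descriptions of these loci were used here, and transposon-related loci could not be set apart for the same reason. The rule names Waxy in full, the 12 loci with the largest change in each direction among those past the threshold with no overlap between groups, up to 4 members with the smallest p in each list and around Waxy, and, where under 5 loci pass in a direction, the 5 with the smallest p. Lists that passed are shown with 4 members and most others with 2, a split set after the values were seen. The value of 1 member of the reference list that the rule names is not reported here.

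The files used here pair these loci with no gene names. Names in the lists are published names of MSU loci, written down from knowledge of the rice literature, and were checked as far as a table allowed. Of 184 list genes, 111 have a symbol of their own, and 49 of these symbols matched 1 gene of the RefSeq table of assembly ASM3414082v1. For 48 the chromosome was that of the locus name, and for 1, a reference gene that is not named below, it was another. Of 142 pairs of matched genes on 1 chromosome, 134 lay in the same order in both. Called loci outside the lists have no name here, and only 2 identifiers in each direction are printed.

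On simulated data with 200 changed loci of 28945 and the spread of these arrays, 10 simulations of this comparison recovered 0% of changes of 1 or 2 on the log2 scale and 93.4% of changes of 4, with 4.26% false calls among those at 4. Lists without a change fell under a camera p of 0.05 in 4% to 5.6% of tests. The simulated loci varied independently of each other, so this share does not show how lists whose members vary together behave. Shifts shared by many loci of an array were thus not simulated. In the real data, high-amylose replicates 2 and 3 differed from the rest at 223 loci. Fitted array weights ran from 0.223 for high-amylose replicate 1 to 7.67 for high-amylose replicate 2. The shares recovered and falsely called therefore describe the simulated data only, and are not rates of the real comparison.

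Alternatives covered normexp background correction with an offset of 50, quantile and median scaling, the deposited log2 table, 2 other filters on dim probes, 2 other treatments of probes per locus, the variance prior, array weights, 2 other thresholds and leaving out each array. The deposited output has no mean-signal column, so normexp ran on the median signals. Scan dates put high-amylose replicate 1 alone, high-amylose replicates 2 and 3 together, and both waxy arrays together, and each array lay on a slide of its own. No date held both groups, so the planned fixed block could not be fitted, and the date was used as a random block. A window of 1 Mb around Waxy needs coordinates and was replaced by Waxy and the 100 array loci on each side. No group has the 4 or more samples that an outlier test needs.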

Results

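Transcripts of developing seed, 16 days after flowering, were compared between 3 rice accessions with high-amylose grain (haplotype 8) and 2 with waxy grain (haplotype 4), on 1 array each. The 75th percentile of the processed signal, a measure of array brightness, was 183, 108 and 88.8 on high-amylose replicates 1, 2 and 3 and 203 and 212 on waxy replicates 1 and 2. Spots well above background made up 57.9%, 50.2% and 50.4% of the spots on the high-amylose arrays and 58.7% and 58.5% on the waxy arrays, and no spot was saturated. High-amylose replicates 2 and 3, which shared a scan date, were thus dimmer than the other 3 arrays. Across loci, high-amylose replicate 1 correlated at 0.952 and 0.955 with the waxy arrays and at 0.928 and 0.901 with the other high-amylose arrays, and the waxy arrays correlated at 0.956 with each other. Loci are not independent replicates, so these correlations only describe the arrays.

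The first measurement concerned Waxy (LOC_Os06g04200), which encodes the granule-bound starch synthase GBSSI that makes amylose in the endosperm and whose alleles underlie waxy grain. The Waxy transcript was far lower on 1 of the 2 waxy arrays only. Relative to each array's 75th percentile, its log2 signal was 7.96, 8.46 and 8.32 on the high-amylose arrays (SD 0.26, n = 3), 8.21 on the array labelled waxy replicate 1 and 3.70 on waxy replicate 2. Waxy replicate 2 lay 23.4-fold below the high-amylose mean, and waxy replicate 1 lay within 1.03-fold of it. The waxy arrays thus differed 22.8-fold from each other at this locus, and 72 of 28945 loci differed by as much between them. As a group difference, Waxy was 2.29 higher in high-amylose seed on the log2 scale (SE 1.04), which did not pass (limma with Benjamini-Hochberg, adjusted p = 1.00). Without waxy replicate 1 the difference was 4.55, and without waxy replicate 2 it was 0.04. Each of these fits leaves 1 waxy array, so it holds no spread between waxy accessions. The locus has 1 probe on the array, in 1 spot.

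Across the transcriptome, 8 of 28945 loci differed between the groups, 3 higher and 5 lower in high-amylose seed. Both waxy arrays were scanned on a date that no high-amylose array shared, so group and scan date cannot be told apart at these loci. Dihydroflavonol 4-reductase, or DFR (Rd, LOC_Os01g44260), an enzyme of anthocyanin and proanthocyanidin synthesis and a gene of red pericarp colour, was the only one of the 8 on any of the gene lists. It was 22.0-fold higher in high-amylose seed, where its log2 signal was 0.40, -0.33 and 1.27, against -3.77 and -4.26 in waxy seed, where it was not well above background. Both waxy values lay above their array's lowest signal well above background, so this fold is the measured one and not a lower limit. The fitted DFR difference was 4.46 (SE 0.53, limma with Benjamini-Hochberg, adjusted p = 0.0406). With every probe tested apart, neither of its 2 probes passed. The probe used here was at 4.46 (limma adjusted p = 0.0550) and the second at 3.28 (limma adjusted p = 1.00). LOC_Os08g30014 on chromosome 8 and LOC_Os10g19894 on chromosome 10 rose at least 23.5-fold and 12.1-fold, with fitted log2 differences of 4.88 (SE 0.48) and 4.80 (SE 0.49), each at a limma adjusted p of 0.0160.

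The 5 loci that fell were all below clear detection on every high-amylose array and well above background on both waxy arrays. LOC_Os12g38550 on chromosome 12 was at least 27.0-fold lower, with a fitted log2 difference of -6.37 (SE 0.45, limma adjusted p = 0.00362). Its neighbour on the array was at least 9.80-fold lower, at -4.85 (limma adjusted p = 0.0111). LOC_Os11g37774 on chromosome 11 was at least 19.6-fold lower, at -5.57 (SE 0.43, limma adjusted p = 0.00389). A further locus of chromosome 12 was at least 7.50-fold lower (-4.11, limma adjusted p = 0.0160) and another of chromosome 11 at least 5.58-fold lower (-3.89, limma adjusted p = 0.0401). The positive differences with the smallest p after the 3 that passed were 3.81 on chromosome 7 and 3.86 on chromosome 9, neither of which passed (limma adjusted p = 0.0690 for both). At all 8 called loci the 3 high-amylose arrays did not overlap the 2 waxy arrays. Groups did not overlap at 3922 loci (13.6%), against 20% by chance, and 983 loci (3.40%) had an unadjusted limma p under 0.05, where chance gives 1447.

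The number and direction of called loci changed with single arrays. Without high-amylose replicate 1, 3 called loci were higher and 6 lower, while without replicate 2 or without replicate 3, 0 were higher. Leaving out 1 array gave 9 called loci without high-amylose replicate 1 (5 of the 8 among them), 5 without replicate 2 (3 of the 8), 3 without replicate 3 (2 of the 8), 72 without waxy replicate 1 (all 8) and 179 without waxy replicate 2 (all 8). With high-amylose replicates 2 and 3 given a term of their own, or left out, limma called 0 loci, with 1162 and 1663 at an unadjusted p under 0.05. Quantile scaling called 3 loci, 0 higher and 3 lower, all of them among the 8. The DFR call was lost without high-amylose replicate 1, 2 or 3 (limma adjusted p = 0.113, 0.0512 and 0.171). Its fitted difference was then 4.48, 4.85 and 4.05, against 4.46 with all arrays. Under normexp on median signals with quantile scaling, the fitted differences of all 8 called loci were smaller in size. There DFR was at 1.84, LOC_Os10g19894 at 1.14 against 4.80, and LOC_Os12g38550 at -2.75 against -6.37. Quantile scaling without normexp left DFR at 4.36. The folds given above thus do not carry over to normexp. Its offset of 50, added before log2, exceeds the median processed signal of every array (14.9 to 35.3). Adding it shrinks differences at loci that are dim in a group, by construction. The smaller sizes are therefore no separate check of these loci.

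**Figure D1:**
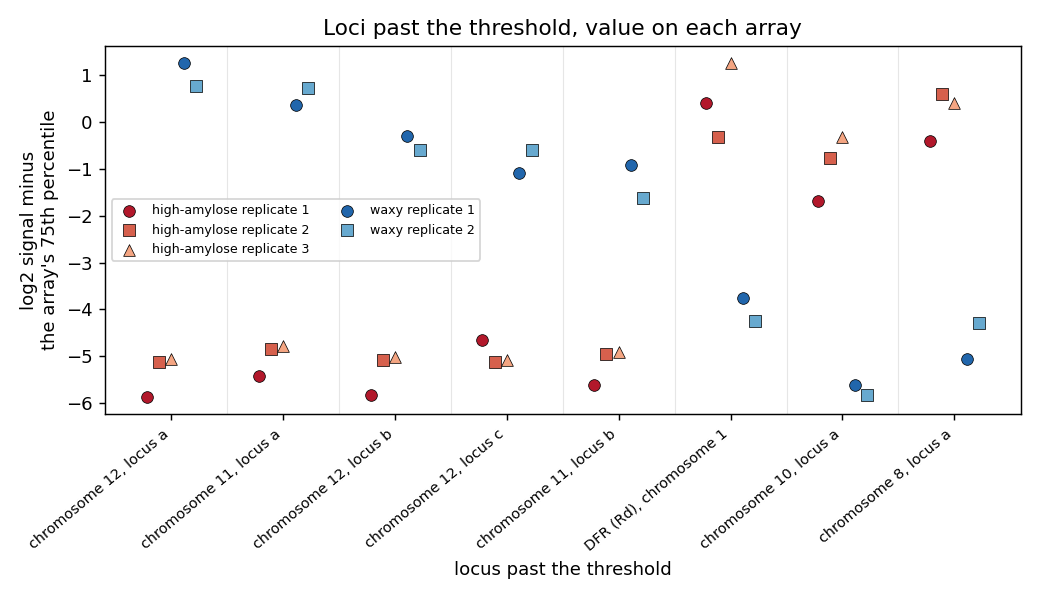
Signal of the 8 loci past the threshold on each of the 5 arrays, as log2 of the processed signal minus the array's 75th percentile, with a point for each array and letters for loci of 1 chromosome. For the 5 loci that fell, every high-amylose array lies below every waxy array, and for the 3 that rose every one lies above.

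For the starch synthases, fixed as a list beforehand, 8 of 10 loci were tested. Waxy at 2.29 was the member that differed most, and no member passed, over all loci or adjusted over the list alone. Of the 8, 4 were higher and 4 lower, with a median log2 difference of -0.00, a mean of 0.26 and an upward direction as a set that did not pass (camera adjusted p = 0.804). SSIIIb, the leaf form of a soluble starch synthase, was at 0.44 (SE 0.44).

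Starch branching and debranching enzymes and phosphorylases, which shape amylopectin, were lower at 7 of 10 loci, with a median of -0.57. The set did not pass (camera adjusted p = 0.114), nor did any member over all loci or adjusted over the list alone. The branching enzyme BEIIa was at -0.88 (SE 0.48) and the disproportionating enzyme DPE1 at -0.96 (SE 0.64). On high-amylose replicates 1, 2 and 3 the median member deviated by 0.64, -0.61 and -0.43 from its mean over all arrays, and on the waxy arrays by 0.14 and 0.40. The list passed downward without high-amylose replicate 1 (camera adjusted p = 0.000495), with no filter on dim probes (0.0152) and with the filter on all 5 arrays (0.0472). With high-amylose replicates 2 and 3 given a term of their own, which sets replicate 1 alone against the 2 waxy arrays, it was shifted upward instead (camera adjusted p = 0.0424). These passes rest on the preset correlation, and over all 5 arrays the camera adjusted p with an estimated correlation was 0.973.

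ADP-glucose and sugar supply, which feeds starch synthesis, had 6 loci higher and 9 lower of 15, with a median of -0.28, a mean of 0.05 and a downward camera adjusted p of 0.819. GIF1 (LOC_Os04g33740), a cell-wall invertase of grain filling, was 2.88 higher in high-amylose seed (SE 0.66). It passed adjusted over the list alone, as the 1 member that did, and not over all loci (limma adjusted p = 0.589), and it passed among the loci well above background on all 5 arrays (limma adjusted p = 0.00462). The sucrose synthase SUS2 was at 0.88 (SE 0.44). This list too passed downward without high-amylose replicate 1 (camera adjusted p = 0.0392) and upward with a term for replicates 2 and 3, where replicate 1 alone stands for high-amylose seed (camera adjusted p = 0.00154). Both passes rest on the preset correlation, and over all 5 arrays the camera adjusted p with an estimated correlation was 0.973. Of 9 endosperm regulators, 7 were higher and 2 lower, with a median of 0.09 (camera adjusted p = 0.804). None passed over all loci or adjusted over the list alone. NF-YB1, an endosperm transcription factor, was at 1.12 (SE 0.46) and Du1, a splicing factor of Waxy pre-mRNA, at -0.50 (SE 0.44).

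**Figure D2:**
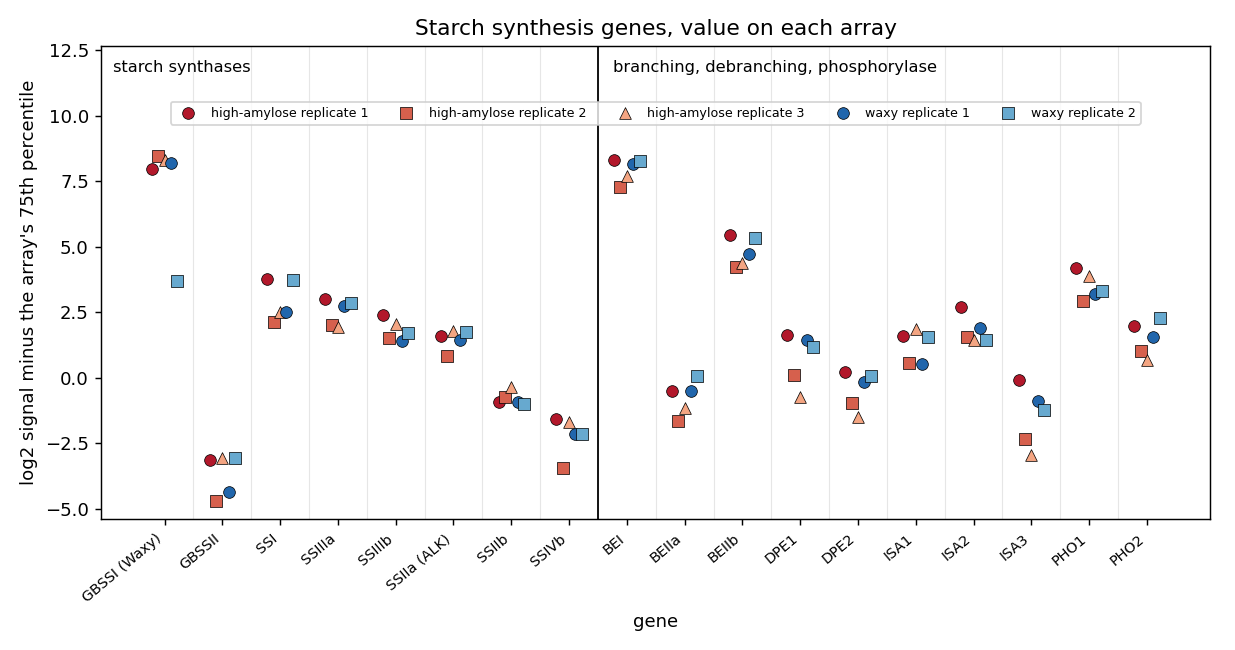
Signal of 18 starch synthesis genes on each of the 5 arrays, as log2 of the processed signal minus the array's 75th percentile, with a point for each array. Levels compare arrays within a gene and not genes with each other, since each gene has its own probe. Waxy replicate 2 lies at 3.70 for Waxy, apart from the other 4 arrays at 7.96 to 8.46.

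Photosynthesis genes, markers of the green outer layers of the seed, were higher in the high-amylose group at all 16 loci tested, with a median log2 difference of 1.87, or 3.64-fold (camera adjusted p = 2.85e-10). With an estimated correlation the camera adjusted p was 0.973, and the fry adjusted p was 0.983. For 4 of the 16 loci the waxy arrays were not well above background, and with these at their bound the median was 1.75. No single locus passed over all loci or adjusted over the list alone. The antenna protein gene LHCA (LOC_Os08g33820) was at least 3.87-fold higher. LHCB (LOC_Os07g37240), another antenna protein gene, was 4.34-fold higher as measured, with no lower limit applied. Both were detected on 2 of the 3 high-amylose arrays. A second LHCB (LOC_Os07g37550) was at 2.03 (SE 0.92) and PSBP, of the oxygen-evolving complex, at 2.19 (SE 0.99). The higher signal lay in high-amylose replicates 2 and 3, the dimmer arrays, where the median locus deviated by 1.12 and 2.52 from its mean over all arrays. On high-amylose replicate 1 it deviated by -1.19, and on the waxy arrays by -1.30 and -0.92. With replicates 2 and 3 left out, the list was lower in high-amylose seed and did not pass (camera adjusted p = 0.161).

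Flavonoid pathway genes, which make the pigments of the pericarp, were higher at all 9 loci, with a median log2 difference of 1.21, or 2.31-fold (camera adjusted p = 6.82e-05). With an estimated correlation the camera adjusted p was 0.973 here too, and the fry adjusted p was 0.966. Among loci well above background on all 5 arrays the list did not pass (camera adjusted p = 0.104). DFR alone passed, over all loci and adjusted over the list alone. Anthocyanidin reductase, ANR, was at 1.21 (SE 0.50) and chalcone synthase, CHS, at 2.00 (SE 1.17). Rc, the regulator of red pericarp, was at least 3.45-fold higher, detected on 2 of the 3 high-amylose arrays. The median member deviated by -0.29, 0.68 and 1.30 on high-amylose replicates 1, 2 and 3 and by -0.23 and -0.39 on the waxy arrays, so this list also stood highest on the 2 dimmer arrays. DFR and ANR differed from that pattern, each with all 3 high-amylose arrays above both waxy arrays. With a term for replicates 2 and 3 the flavonoid list did not pass (camera adjusted p = 0.951).

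**Figure D3:**
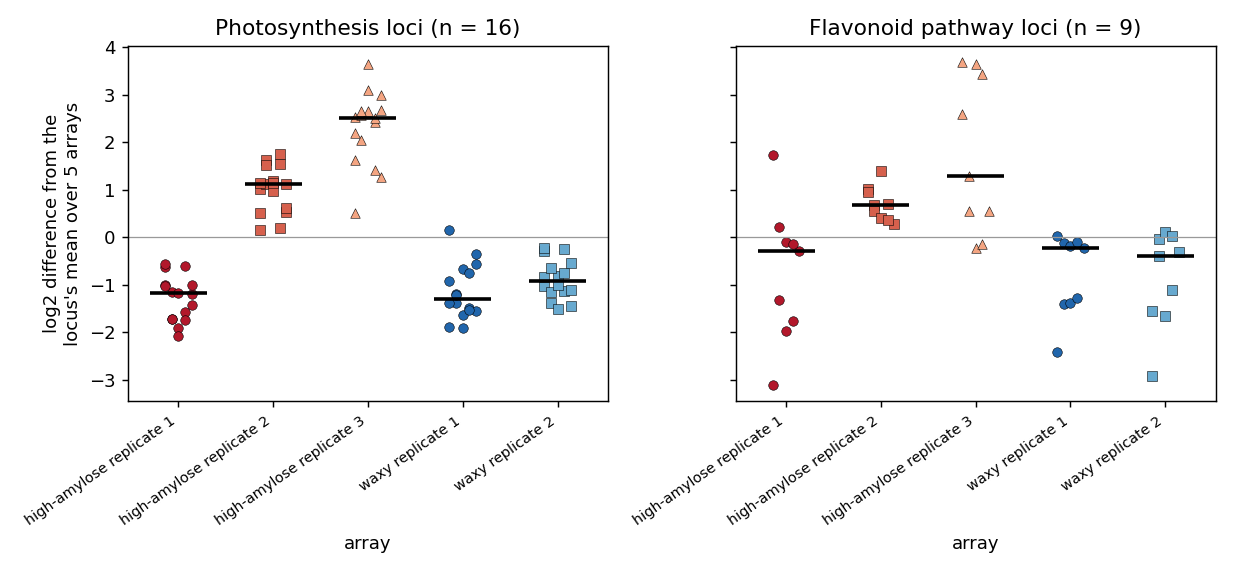
Deviation of each photosynthesis locus (n = 16) and each flavonoid pathway locus (n = 9) from its own mean over the 5 arrays, on the log2 scale, with a point for each locus and a bar at the median. The photosynthesis medians are 1.12 and 2.52 on high-amylose replicates 2 and 3 and lie between -1.30 and -0.92 on the other 3 arrays.

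Storage protein genes did not pass as sets. Prolamins, alcohol-soluble storage proteins, were higher at 9 of 13 loci, with a median of 0.22 (camera adjusted p = 0.152), and the members with the smallest p were a pair of 13 kDa prolamins at 1.34 (SE 0.64) and 0.97 (SE 0.51). Glutelins, the main storage proteins of rice, were higher at 8 of 10 loci, with a median of 0.19 (camera adjusted p = 0.428), a direction that turned under normexp, quantile scaling and the deposited log2 values. GluB-6 was at 0.59 (SE 0.42) and GluA-3 at 0.41 (SE 0.43). Globulins and seed allergens were higher at 6 of 9, with a median of 0.10 (camera adjusted p = 0.623), and turned under the same 3 settings. Allergen family members were at -0.50 (SE 0.43) and at 0.51 (SE 0.44), the latter near 0 with the opposite sign under quantile scaling and in the deposited log2 values. Cross-hybridisation between near-identical copies in these families was not tested, so values of single members are uncertain.

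Markers of embryo and aleurone, the other main tissues of the seed, were higher at 9 of 12 loci with a median of 0.08 (camera adjusted p = 0.623), a direction that turned under normexp, quantile scaling and the deposited log2 values. Among them 1-Cys peroxiredoxin was at 0.54 (SE 0.44) and the oleosin OLE16 at 0.47 (SE 0.60). Heat shock and chaperone genes were higher at 13 of 21, with a median of 0.05 (camera adjusted p = 0.819), and turned under the same 3 settings. The endoplasmic chaperone BiP1 was at 0.66 (SE 0.50) and a small heat shock protein at 0.77 (SE 0.61). Enzymes of starch breakdown were lower at 9 of 14, with a median of -0.08 (camera adjusted p = 0.623), the glucan-water dikinase GWD1 at -0.61 (SE 0.53) and the alpha-amylase RAmy2A at -0.35 (SE 0.45). Sugar transporters were higher at 3 of 7, with a median of -0.04, a mean of 0.00 and an upward camera adjusted p of 0.946, SUT1 at 0.61 (SE 0.43) and SWEET15 at -0.67 (SE 0.52). Reference genes, often used as internal controls, were higher at 4 of 9, with a median of -0.06 (camera adjusted p = 0.889), and GAPDH was at 0.69 (SE 0.41). No member of these lists or of the storage protein lists passed, over all loci or adjusted over the list alone. As sets, embryo and aleurone markers passed upward without high-amylose replicate 3 (camera adjusted p = 0.00471), and starch breakdown downward without high-amylose replicate 2 (camera adjusted p = 0.0367). Starch breakdown was also shifted downward with a term for replicates 2 and 3 and with both left out, where replicate 1 alone stood for high-amylose seed. Heat shock genes were shifted upward without waxy replicate 2 and downward without waxy replicate 1, where 1 waxy array remained. These passes rest on the preset correlation, and over all 5 arrays each of the 3 lists had a camera adjusted p of 0.973 with an estimated correlation.

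The last comparison asked whether called loci lay near Waxy or gathered on a chromosome, since alleles of Waxy underlie waxy grain. None of the 8 lay on chromosome 6, which holds Waxy, and neither Waxy nor any of the 151 tested loci among the 100 array loci on each side of it passed. Fits without either waxy array leave 1 waxy array, so their calls around Waxy are not weighed here. Of these 151, 8 (5.30%) had an unadjusted limma p under 0.05, against 3.40% of all loci. The smallest p there belonged to a locus 57 array loci from Waxy, at least 3.28-fold lower in high-amylose seed. Its fitted difference was -2.76 (limma adjusted p = 0.112), and -2.84 without waxy replicate 2. The next was at -1.66 (limma adjusted p = 0.867). Chromosome 12 held 3 of the 8 called loci, which did not pass over the 13 regions tested (Fisher's exact test, two-sided, p = 0.00911, adjusted p = 0.119), and chromosome 11 held 2 (exact p = 0.0784, adjusted p = 0.510). The chromosome 12 loci include LOC_Os12g38550 and its neighbour on the array. The exact test takes loci as independent and counts such neighbours apart, here and in the settings below. With the arrays scaled by their medians instead, 6 loci were called and chromosome 12 passed (exact test, adjusted p = 0.0463), as it did without high-amylose replicate 2 (0.0242). Without waxy replicate 2 chromosomes 2 and 8 passed instead.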

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

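Tests with the scan date as a random block, with a term for high-amylose replicates 2 and 3, with both left out, with 300 or 500 loci on each side of Waxy, and with Waxy left out of its window were chosen only after the data were seen. No paired analysis was possible because the replicate numbers follow the order of the deposits and each array is another accession. Fixed-date blocking and windows of 1, 3 and 5 Mb around Waxy were not run. Where leaving out an array left 1 waxy array, or high-amylose replicate 1 alone (with the term or with both arrays left out), limma assumed that the lone array varies like the others. Against 8 called loci, normexp gave 0 in limma (650 at an unadjusted p under 0.05), quantile scaling 3 (0 higher, all of the 8), the deposited log2 values 3 (0 higher, all of the 8), the filter on all 5 arrays 21 (11 higher), trend and robust 22 (12 higher, 7 of the 8), array weights 2754 (1016 higher), and an adjusted p under 0.1 14. The count of separated loci was 3922, or 13.6% of loci, which is below the 20% that chance gives. A term for high-amylose replicates 2 and 3, or both left out, gave 0 and 0, with fewer degrees of freedom or arrays. Leaving out each array gave 3 to 179. The filter on all 5 arrays tested 22597 loci and, by its construction, none of the 8, which were each undetected in a group. The array weights were very uneven (7.67 for high-amylose replicate 2 against 0.223 for replicate 1 and 0.332 for replicate 3). The high-amylose mean of that fit thus rests mostly on replicate 2. Why the counts moved was not tested. The random block (correlation 0.180) gave 6, all of the 8, median scaling 6, no filter 6, the mean of a locus's probes 7, and every probe apart 7. The random block cannot separate the groups from the dates, since no date held both groups. Without a filter on dim probes the median of all loci moved from 0.03 to 0.208, so changes there are relative to that shift. Dim signal limits the folds of the called loci other than DFR to bounds. Under normexp the fitted differences of all 8 were smaller in size, which its offset brings about by construction at loci that are dim in a group.

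DFR passed with trend and robust, with array weights and without either waxy array, was not tested under the filter on all 5 arrays, and did not pass under the other 13 settings run for it. Its limma adjusted p ranged from 2.73e-05 to 1 over the alternatives. The Waxy difference ranged from 0.0398 to 4.55 when an array was left out. It was 4.55 without waxy replicate 1, where 1 waxy array remained. The number of lists that passed was 2 to 4 when an array was left out, with starch branching at 0.000106 and ADP-glucose supply at 0.0112 without high-amylose replicate 1, 0 with an estimated correlation and 0 with fry. Regions past the threshold numbered 1 under median scaling (chromosome 12) and 0 to 2 when an array was left out. Normexp called no locus and so gave no value for regions. Photosynthesis gave an unadjusted p of 0.161 with an estimated correlation and 0.312 with fry, and turned downward at 0.171 with the term and 0.103 with both arrays left out. Flavonoid genes gave 0.0283 under the filter on all 5 arrays, 0.848 with the term, 0.10 with an estimated correlation and 0.138 with fry, and turned downward at 0.639 with both arrays left out.

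With the term, and with both arrays left out, the direction of other lists also turned. The p-values were 0.00011 and 9.51e-05 for ADP-glucose supply (upward), 0.00744 and 0.00596 for starch branching (upward), 0.127 and 0.103 for reference genes, and 0.0660 and 0.0836 for sugar transport. The same 2 settings turned Rc (-0.44), CHS (-0.56), an allergen (-0.0249), PSBP (-0.26), BiP1 (-0.15), a small heat shock protein (-0.26) and DPE1 (0.35). Quantile scaling and the deposited values turned that allergen (-0.0265 and -0.0331). Other turns of lists had camera p-values under normexp of 0.693 (embryo and aleurone), 0.0201 (globulins and allergens), 0.902 (glutelins) and 0.789 (heat shock). In that order they were 0.926, 0.278, 0.840 and 0.867 under quantile scaling, and 0.851, 0.257, 0.582 and 0.856 for the deposited values. Without a filter they were 0.665 (embryo and aleurone), 0.570 (endosperm regulators), 0.799 (globulins and allergens), 0.218 (heat shock), 0.230 (starch synthases) and 0.412 (sugar transport). ADP-glucose supply turned at 0.936 and sugar transport at 0.806 under the filter on all 5 arrays, and ADP-glucose supply at 0.973 with the mean of probes. Ranges over left-out arrays that hold a turn were 0.0112 to 0.587 (ADP-glucose supply), 0.000673 to 0.825 (embryo and aleurone), 0.179 to 0.794 (endosperm regulators), 0.00493 to 0.675 (heat shock), 0.315 to 0.809 (reference genes), 0.00786 to 0.862 (starch breakdown), 0.0262 to 0.906 (starch synthases), 0.268 to 0.918 (sugar transport), and log2 -1.35 to 0.0130 (SWEET15). The cause of these turns was not tested.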

Other observations

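The comparisons of high-amylose replicates 2 and 3 with the other 3 arrays, with and without values at their bound or floor, and the tests of array signal, of the number of Waxy probes, of endosperm share, of scan date, of chance placement, with and without matching on detection, and of probe name classes, were chosen only after the result was seen. The tests of a mislabelled array, of matched lists, of a shared direction of neighbours and of other splits were set before their own results were known. All but that of other splits concern patterns first seen in these data. The matched lists also used the comparison of high-amylose replicates 2 and 3 with the other 3 arrays.

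High-amylose replicates 2 and 3 differed from the other 3 arrays at 223 loci, 62 higher and 161 lower (limma with Benjamini-Hochberg), and 0 of these were among the 8 loci called between the groups. Of the 16 photosynthesis loci 7 passed, all higher. The other 3 arrays were not well above background at 4 of the 16, 2 of them among the 7, and with these at their bound the list's median was 2.85 higher on the log2 scale. High-amylose replicate 2 lay above high-amylose replicate 1 and both waxy arrays at 15 of the 16 loci and replicate 3 at 16, while high-amylose replicate 1 differed from the waxy arrays by a median of -0.23. An LHCB gene well above background on all 5 arrays (LOC_Os03g39610), singled out after its values were seen, was at 1.81 and 3.69 on these arrays and at -0.74, -0.87 and -0.42 on the others. Genes of the flavonoid pathway were higher at 9 of 9 loci with a median of 1.54, and 1 passed. Starch branching and debranching enzymes and phosphorylases were lower at 10 of 10 loci with a median of -0.96, and ADP-glucose and sugar supply was lower at 13 of 15 with a median of -0.67, though no member of either list passed. Embryo and aleurone markers had a median of 0.07. These 2 arrays are samples that stand apart and not a group of the study.

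The high photosynthesis signal on these 2 arrays was weighed against 3 technical explanations. Their lower brightness alone was argued against, since the list's median lay 2.51 (log2) above the upper limit of the central range of 10000 lists matched on mean signal, and 2.35 above it with all values raised to each array's lowest detected signal. A lower share of endosperm RNA, if it raised all other seed tissues alike, would raise embryo and aleurone markers too. Their shift was -2.93 from that of photosynthesis (bootstrap SE 0.262). With all values raised to each array's lowest detected signal it was -2.77 (bootstrap SE 0.248). The bootstrap drew loci, so its SE does not cover the spread between arrays or accessions. These values argue against such an even rise, and not against a lower endosperm share in which other tissues rose unevenly. The scan date cannot be told apart from the accessions, because its 2 arrays are the only ones of that date. A candidate explanation is that these accessions held more, or greener, outer seed tissue at sampling, as with slower development, and this stays open and untested, as does a difference in how seed was collected.

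The Waxy transcript on the array labelled waxy replicate 1 lay at the high-amylose level. Weaker signal on waxy replicate 2 was argued against by 64 other starch and storage protein loci, whose median difference between the waxy arrays was -0.0015, the lowest being -1.06 against -4.51 for Waxy. A mislabelled array stays possible: where waxy replicate 2 differed by 3 or more on the log2 scale from a pair of high-amylose arrays, waxy replicate 1 passed the midpoint towards it in 54.5% of 209 comparisons over the 3 pairs, in which a locus can count once per pair, and at 54.7% of the 106 loci of the pair of replicates 2 and 3, against 55.7% for left-out high-amylose replicate 1. The pairs disagreed, since in the other pairs the shares were 60.4% against 30.2% for left-out replicate 2 and 48% against 24% for replicate 3. High-amylose replicate 1 correlated more with the waxy arrays (0.952 and 0.955) than with its own group (0.928 and 0.901). The pair of replicates 2 and 3 therefore cannot decide on a mislabelled array. A sequence difference under the probe cannot be told apart, as the locus has 1 probe, and different waxy alleles, with and without a stable transcript, may be the source and were not tested.

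Loci with small p lay near each other more often than in random draws. Among the 100 loci with the smallest p, 7 pairs lay within 5 array loci of each other, against a mean of 1.1 and a highest of 7 in 10000 random draws (permutation p = 3e-04). Of the 100, 72 were not well above background on any array of 1 group, against 2.17% of all loci, and draws matched on this had a mean of 1.17 and a highest of 6 (permutation p = 1e-04, the smallest these draws can give), which argues against chance placement. Probes of the JMULT and JXHYB name classes alone did not account for it, since JUNQ probes gave 8 pairs against a highest of 6 in random draws and 7 in matched ones (permutation p = 1e-04 in both), though this explanation was worded after its result was seen and similar sequence among neighbours was not tested. All 7 pairs differed in the same direction (100%), against 51.5% of all neighbouring loci and 59.9% of the pairs in matched draws, and chromosome segments that differ between the haplotype groups may underlie them, which is a hypothesis found on the same data.

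Of the 10 splits of the 5 arrays into 3 and 2, 2 gave at least the 8 called loci of the real one, the real one included. Splits that mixed the groups came close. The pair of high-amylose replicate 1 and waxy replicate 2 gave 7, and that of high-amylose replicate 2 and waxy replicate 1 gave 6. The other pairs of 1 array from each group gave 0 or 1. With 10 splits a share under 0.05 cannot be reached. The highest other split, with 223, set high-amylose replicates 2 and 3 against the rest and so followed the scan date, and its count points to a structure of the samples. No date held both groups, so no value within a date can be had. The random block gave 6 called loci but, for the same reason, cannot separate the groups from the dates.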
